A study of Mus musculus with 3 samples.

How the data were processed

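Fetal liver RNA of mouse embryos at stage E14.5 was profiled on 3 CodeLink arrays, 1 for each of 3 genotypes: wild-type, DNase II-deficient, and double-deficient in DNase II and IFN-IR. Per the labels' protocols, poly(A) RNA was selected from total RNA, copied into double-stranded cDNA and transcribed in vitro with a biotinylated nucleotide. The labelled RNA was hybridised and stained with streptavidin carrying Cy5, and the image was analysed with the CodeLink System Software, per the labels' protocols. The software's version, its background method and its filters are not given in the sources used here.

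The values deposited by the authors are normalised intensity on a linear scale, 1 value per probe and array. Their medians were 0.958, 0.959 and 0.963 in the wild-type, DNase II-deficient and double-deficient arrays, so the arrays already shared a typical level, and 267, 224 and 253 values per array were at or below 0, as background subtraction leaves. A common scale of this kind hides any difference in total RNA and makes each level relative to the array's typical probe. Dim probes are uncertain, because a subtracted background leaves mostly noise. No depth exists for an array, and precision is limited by the number of arrays. Of 20289 probes, 125 lacked a value in at least 1 array and were left out.

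Probe names came from the platform annotation supplied with the values, which can be old: 15120 probes had 1 gene symbol, 38 had several and 5131 had none. Probes with several or no symbols named no gene. Entrez identifiers of 15064 probes matched the reference gene table, and 0 symbols needed an update. Where a gene had several probes (1244 genes), the probe with the highest mean log2 level stood for it. Genomic positions of probes were not used here.

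Values were used as deposited, set to the array's 25th percentile where lower, and log2 transformed. A gene entered a comparison where it lay above the array median in at least 1 of the 2 arrays. The comparisons were DNase II-deficient minus wild-type, double-deficient minus DNase II-deficient and double-deficient minus wild-type. With 1 array per genotype no test, standard error or p-value was computed. Genes were counted at 2-fold and 4-fold. Where the lower array was at its floor, the fold is a lower bound and is given as at least that value. The spread around a gene's level is 1.4826 times the median absolute deviation of the difference over the 500 genes nearest in mean level, a description of these arrays and not of replicates.

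Before the data were examined, 25 gene lists were fixed: interferon-stimulated genes, interferon-inducible GTPases, MHC class I and antigen processing, interferon genes, inflammatory cytokines and chemokines, nucleic acid sensing, erythroid genes, embryonic globins, heme biosynthesis, macrophage markers, lysosomal genes, complement genes, hepatocyte genes, acute phase genes, megakaryocyte and platelet markers, granulocyte and mast cell markers, stem and progenitor markers, lymphoid markers, endothelial markers, mesenchymal markers, cell cycle genes, p53 targets and cell death, hypoxia genes, housekeeping genes and sex-linked genes. Only Pgk1 was in 2 lists. The members Rigi and Hbb-b1 were looked up under the array's symbols Ddx58 and Hbb-bt, a step added after the probe names were seen. A list median was taken over members above the floor in at least 1 of the 3 arrays, without the level filter, and was given its percentile among 10000 random lists of the same size matched on mean level in 20 bins. A list stood apart at a percentile of at least 99 or at most 1, with at least 5 measured members. Counts of 2-fold members do use the level filter. The interval of a list median came from 2000 bootstrap draws of its members. Reversal in the double mutant was set against 100 simulations of 3 arrays without genotype effects, with the noise of the differences between the double-deficient and wild-type arrays.

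The genes named were fixed by rule before the data were examined: the targeted genes, up to 6 members per list and comparison with the largest difference and up to 2 against the list median, the 12 largest positive and 8 largest negative differences outside the lists for the comparisons involving the array labelled DNase II-deficient (8 and 6 for double-deficient minus wild-type), and the 6 largest lower bounds in each direction. Genes with clone-based names were counted but not named. The list members Usp18, Ifitm3, Ifng, Ccl4, Hba-a1 and Hbb-bt were named after their values were seen.

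The steps were tested on simulated data for DNase II-deficient minus wild-type over 13697 genes with 200 planted differences. Of planted log2 differences, 94.5% of those of 1.5, 100% of those of -1.5, 100% of those of 2.5 and 97.9% of those of -2.5 were called 2-fold different, as was 1 of 7888 unchanged genes. All planted genes were above the level filter in the simulated wild-type array, so the recovery of genes dim in wild-type was not tested. That test used a noise SD of 0.2 on the log2 scale per array, which is small: the simulations without genotype effects, with noise from the arrays that holds real differences too, gave 131.63 higher and 129.74 lower genes on average in this comparison, so false calls can be far more frequent. Of 100 unchanged random lists 2 stood apart. Their genes had independent noise, so this rate need not hold for lists of genes that vary together. As a check within the arrays, genes with several probes above the filter had differences that correlated between probes at 0.57, 0.53 and 0.35 in the 3 comparisons (across 515, 499 and 497 genes, which are not replicates), and the probes went the same way for 33 of 36, 18 of 19 and 5 of 5 genes at least 2-fold different by 1 probe.

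Alternatives were quantile normalisation, scaling to the 75th percentile, cyclic loess, no floor, a floor at the array median, the mean over a gene's probes, no level filter, a filter at the 75th percentile, a 3-fold threshold and each gene kept in 1 list. Centring on the median of the genes compared was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and cyclic loess was run with limma 3.58.1 in R 4.3.3 on values raised to at least 0.01.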

Results

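The messenger RNA of fetal liver from mouse embryos at stage E14.5, given in days of gestation, was measured on 3 single-colour CodeLink oligonucleotide arrays, 1 per genotype. The genotypes were wild-type, DNase II-deficient, and deficient in both DNase II and IFN-IR, the receptor for type I interferon. DNase II is the lysosomal nuclease with which macrophages digest the DNA of engulfed cells, including the nuclei expelled by erythroblasts. The fetal liver at this stage is the main site of red cell formation. How many embryos contributed to each array was not given in the sources used here. With 1 array per genotype there are no replicates, so every difference below is a value with no replicate check and carries no test. The number of arrays limits the precision.

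Of 20289 probes, 20164 had a value in all 3 arrays, and those with a single gene symbol stood for 13697 genes. The deposited intensities had medians of 0.958 in the wild-type array, 0.959 in the array labelled DNase II-deficient and 0.963 in the array labelled double-deficient. Values below the array's 25th percentile, 0.162, 0.159 and 0.163, were set to it. Across probes, which are not independent replicates, the correlation of log2 values was 0.969 between the DNase II-deficient and wild-type arrays, 0.980 between the 2 mutant arrays and 0.990 between the double-deficient and wild-type arrays.

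The targeted genes were examined before the comparisons. The probe for Dnase2a, which encodes DNase II, read 40.4 in the wild-type array, 48.6 in the array labelled DNase II-deficient and 39.7 in the array labelled double-deficient, so it was lower by no more than 0.03 on the log2 scale in either mutant. The probe for Ifnar1, a chain of the type I interferon receptor, read 3.60, 4.66 and 3.17, and that for Ifnar2, the other chain, read 0.574, 0.485 and 0.483. Where these probes lie relative to the deleted parts is not given in the sources used here, and a probe outside the deletion checks nothing. The genotypes therefore rest on the labels alone, and every direction below is that of the arrays as labelled.

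The comparison of the array labelled DNase II-deficient with wild-type asks which genes differ in fetal liver without the nuclease. Genes that respond to type I interferon were far higher in the array labelled DNase II-deficient. Irf7, the transcription factor that amplifies interferon production, read 3.75 in wild-type and 192.6 in the mutant, 51.4-fold higher. The antiviral genes Rsad2, Ifit1 and Oasl1 were 137-fold, 125-fold and 98.2-fold higher. Of 40 measured interferon-stimulated genes, 35 were at least 2-fold higher and none was 2-fold lower, with a median log2 difference of 3.28. That median stood at percentile 100 of random lists of like level, 95% of which lay between -0.34 and 0.03. Usp18, which restrains signalling from the interferon receptor, was 28.0-fold higher, and Ifitm3, among the brightest of the list, went from 23.02 to 388.4. Mx1 was at the floor in wild-type and at least 26.6-fold higher. The exceptions included Ube2l6, at 39.7 and 36.1, and the probes chosen for Oas3 and Parp14, with log2 differences of 0.01 and -0.93. Probes of these last genes did not go together: the other Oas3 probe was higher by 3.71, and the other Parp14 probes by 4.37 and 3.57, on the log2 scale.

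Other groups tied to interferon were higher as well. The interferon-inducible GTPases, which act against intracellular pathogens, had a median log2 difference of 3.31 (percentile 100), with 9 of 12 at least 2-fold higher. Tgtp1 was 131-fold higher, at 0.735 and 96.0, although signal of the near-identical Tgtp2 cannot be separated from it, and Iigp1 was at least 59.4-fold higher. For MHC class I and antigen processing the median was 1.90 (percentile 100) and 11 of 14 members were at least 2-fold higher. B2m, the light chain of class I molecules, read 111.1 and 455.8, and the immunoproteasome subunit Psmb8 was 9.99-fold higher. The peptide transporter Tap1 was at least 29.6-fold higher. The nucleic acid sensing list had a median of 0.65 (percentile 99.97), with 4 of 15 members at least 2-fold higher: Tlr3, Tlr7, Trex1 and Samhd1. The interval of that median, -0.06 to 1.56, included 0. Interferon genes themselves were dim. Ifnb1 read 0.105 in wild-type, below the floor, 0.471 in the array labelled DNase II-deficient and 0.456 in the array labelled double-deficient. Ifng, the type II interferon gene, was below the floor in all 3 arrays. None of the 5 measured interferon genes was counted as 2-fold different, since none passed the level filter with such a difference, and the median of 0.45 did not stand apart (percentile 88.0).

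Inflammatory cytokines and chemokines were also higher, with a median log2 difference of 1.41 (percentile 100) and 13 of 27 members at least 2-fold higher. Ccl5 was 53.1-fold higher, Ccl2 14.3-fold and Ccl12 12.6-fold. Cxcl1 and Ccl7, at the floor in wild-type, were at least 30.2-fold and 21.8-fold higher. Ccl4 was nearly equal, at 8.72 and 8.97, and Cxcl12 read 1.70 and 1.38. Among acute phase genes, which the liver secretes during inflammation, 5 of 16 were at least 2-fold higher and the median was 0.37 (percentile 99.9). The interval of that median, -0.03 to 2.04, included 0. Hamp, the iron-regulating hormone hepcidin, went from 5.43 to 117.7, Serpina3n was 20.1-fold higher and Saa3 11.5-fold higher, while Crp read 17.9 and 15.5. Myeloid markers moved with these groups. Granulocyte and mast cell markers had a median of 1.47 (percentile 100), with 10 of 17 at least 2-fold higher, among them Prtn3, Camp and Ngp at 3.45-fold, 3.41-fold and 3.15-fold. The mast cell and basophil genes Cpa3 and Mcpt8 were lower, with log2 differences of -0.71 and -0.70. Macrophage markers split. Their median was 0.81 (percentile 100), with an interval of -0.07 to 1.42 that included 0. Of 30 members, 13 were at least 2-fold higher, with Fcgr1 at 5.05-fold and Gpnmb at least 13.8-fold, and 3 were at least 2-fold lower. These 3 are genes of resident tissue macrophages: the scavenger receptor Marco was 10.3-fold lower, Cd5l 8.97-fold and the Kupffer cell lectin Clec4f 7.16-fold lower. Lysosomal genes had a median of 0.57 (percentile 100), with 4 of 25 at least 2-fold higher and 1, Acp5, 2-fold lower. Complement genes did not stand apart (median 0.09, percentile 85.6), although C3ar1 was 21.7-fold and C4b 7.24-fold higher. With the floor at the array median their median was 0.85 and stood apart (percentile 99.9).

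Erythroid genes were lower in the array labelled DNase II-deficient. Of 33 measured, 18 were at least 2-fold lower and none was 2-fold higher, with a median log2 difference of -1.09 (percentile 0). Slc25a37, the mitochondrial iron importer mitoferrin-1, read 147.2 and 33.9, 4.35-fold lower. Trim10 was 4.24-fold lower, the membrane skeleton protein gene Epb42 3.64-fold and the erythroid transcription factor Klf1 2.59-fold. Adult globins were less different: Hba-a1 read 632 and 482, and Hbb-bt 1032 and 894.5, the brightest value of each array. Whether such bright spots were saturated, and whether the Hbb-bt probe is specific to that adult beta globin gene, is not given in the sources used here. The transferrin receptor gene Tfrc went the other way, from 18.6 to 33.5. All 9 measured heme biosynthesis genes were lower, 6 of them at least 2-fold, with a median of -1.06 (percentile 0.01) and Alad at 2.88-fold. The 3 embryonic globins, of the primitive red cells that the yolk sac makes, were higher: Hba-x 2.53-fold, Hbb-y 1.80-fold and Hbb-bh1 1.57-fold. Their number was too small for the comparison with random lists. Cell cycle genes had a median of -0.74 (percentile 0), and 6 of 28 were at least 2-fold lower, among them Ccne1, Rrm2 and Mki67 at 2.84-fold, 2.53-fold and 2.32-fold. Hepatocyte genes stayed near wild-type, with a median of -0.00 over 25 members and 1 gene 2-fold different in each direction, Apoc3 higher and Serpina1a lower. Random lists of like level mostly lay between -0.47 and -0.09, so the list stood above them (percentile 99.7). The sign of that median and the call depended on the scaling: with quantile, 75th percentile and loess scaling it was 0.12, 0.13 and 0.21, at percentiles 97.32, 99.85 and 98.45, so the list stood apart under 75th percentile scaling alone of these. Lists of megakaryocyte and platelet markers (median -0.10, percentile 69.6), stem and progenitor markers (-0.19, 38.7) and lymphoid markers (0.08, 77.9) did not stand apart.

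Genes that respond to low oxygen were higher. Of 14 measured hypoxia genes, 8 were at least 2-fold higher and none lower, with a median log2 difference of 1.32 (percentile 100). Adm, encoding the vasodilator adrenomedullin, was 16.7-fold higher, Ddit4 5.33-fold, Bnip3 4.80-fold and Vegfa 4.46-fold, whereas the glucose transporter gene Slc2a1 read 40.0 and 34.2. The largest positive difference outside the lists belonged to Hspa1a, which encodes the inducible heat shock protein Hsp70. It read 0.509 and 93.3, 183-fold higher, and its near-identical neighbour Hspa1b, whose signal cannot be separated from it, was 42.5-fold higher. Igfbp1, Apln and the stress transcription factor gene Atf3 were 20.4-fold, 19.9-fold and 16.4-fold higher. Among p53 targets and cell death genes the median was 0.61 (percentile 99.99), with 6 of 21 at least 2-fold higher, including Casp4 at 13.3-fold and the cell cycle inhibitor gene Cdkn1a at 8.43-fold, and Perp 2-fold lower. Mesenchymal markers had a median of 0.80 (percentile 99.99), with 5 of 12 at least 2-fold higher, led by the stellate cell gene Lrat at 4.58-fold. The Lrat probe chosen was dim in wild-type, at 0.360 and 1.65, and the other Lrat probe was below the floor in all 3 arrays. Endothelial markers did not stand apart (median 0.16, percentile 94.7), with 3 of 11 at least 2-fold higher and Stab2 lower. Housekeeping genes did not stand apart either (median -0.22, percentile 72.2), and the only member at least 2-fold different was Pgk1, a glycolytic enzyme that the hypoxia list also holds. Of the sex-linked genes, Eif2s3y read 5.07, 11.1 and 8.64 and Kdm5d 5.95, 5.78 and 5.20 in the wild-type, DNase II-deficient and double-deficient arrays, so Y-linked signal was present in all 3. The list had too few members for the comparison with random lists. Its median over 3 measured members was 1.12, and 1 member was counted as at least 2-fold higher. In double-deficient minus wild-type its median was 0.01, the value of a member at the floor in both arrays.

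**Figure D1:**
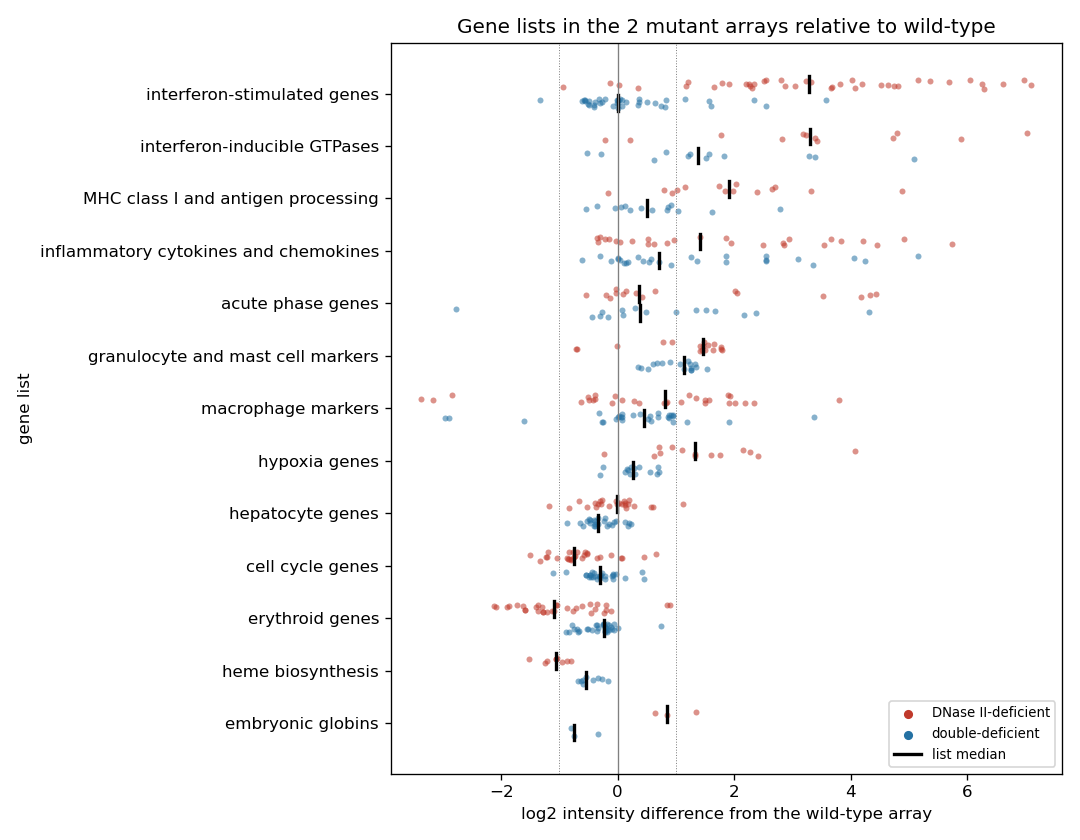
Log2 intensity differences from the wild-type array (horizontal axis) for the measured members of 13 gene lists (vertical axis), with red points for the array labelled DNase II-deficient, blue points for the array labelled double-deficient and black bars for list medians. Interferon-stimulated genes have medians of 3.28 and 0.01, cytokines and chemokines 1.41 and 0.71, and erythroid genes -1.09 and -0.23.

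Other strongly lower genes outside the lists were Car3, at 16.3 and 0.868, Serpina1c, 10.9-fold lower, and the ficolin gene Fcna of macrophages, 8.94-fold lower. The probes for Tert and Cspp1 read 190.4 and 20.1 in wild-type but 0.214 and 0.373 in the array labelled DNase II-deficient, and 0.307 and 0.424 in the array labelled double-deficient. Each rests on 1 probe. Among 8383 genes compared, 643 were at least 2-fold higher and 517 at least 2-fold lower in the array labelled DNase II-deficient, and 223 and 46 were at least 4-fold higher and lower. Higher genes made up 55.4% of those calls as deposited, but 65.8% after quantile normalisation, 67.1% after scaling to the 75th percentile, 72.5% after cyclic loess and 73.6% after centring. The median difference of all genes compared was -0.21 as deposited, against -0.07, -0.07 and -0.00 under the first 3 of these. It was -0.26 with a filter at the 75th percentile. Relative to that median the lists of erythroid, heme biosynthesis and cell cycle genes lay at -0.89, -0.85 and -0.54, and interferon-stimulated genes at 3.48. The typical spread of the log2 difference among genes of like level was 0.49.

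The comparison of the 2 mutant arrays asks what the loss of the interferon receptor alters in the absence of DNase II. Interferon-stimulated genes were far lower in the array labelled double-deficient than in the array labelled DNase II-deficient. Rsad2 was 77.8-fold lower, Irf7 71.9-fold, Sp100 58.9-fold and Rtp4 58.3-fold. Of the 40 measured members, 34 were at least 2-fold lower and none 2-fold higher, with a median log2 difference of -2.94 (percentile 0). Interferon-inducible GTPases (median -1.81, percentile 0, 9 of 12 at least 2-fold lower) and MHC class I and antigen processing genes (median -1.56, percentile 0, 9 of 14) were lower too. Gbp3 was 8.91-fold and B2m 3.76-fold lower. Cytokines and chemokines differed less, with a median of -0.34 (percentile 0) and 7 of 27 at least 2-fold lower, Il15 and Cxcl2 among them. Ccl5 read 11.1 and 7.38, and Cxcl9 1.18 and 1.65.

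Erythroid genes were higher in the array labelled double-deficient than in the array labelled DNase II-deficient, with a median of 0.75 (percentile 100). Of 33 members, 11 were at least 2-fold higher, led by Slc25a37 at 3.45-fold, Epb42 at 3.14-fold and Sptb, the erythrocyte spectrin gene, at 2.80-fold, and 1, Cited2, was 2-fold lower. All 9 heme biosynthesis genes were higher, none by 2-fold (median 0.54, percentile 99.3). Embryonic globins were lower: Hba-x 4.40-fold and Hbb-y 3.03-fold. Hypoxia genes had a median of -0.87 (percentile 0), with 6 of 14 at least 2-fold lower, among them Adm at 14.8-fold and Vegfa at 3.97-fold. Hspa1a was 40.9-fold lower. Mesenchymal (-0.58) and endothelial (-0.51) markers, p53 targets and cell death genes (-0.31), granulocyte and mast cell markers (-0.28), acute phase genes (-0.23), lysosomal genes (-0.23), hepatocyte genes (-0.20) and macrophage markers (-0.12) had medians below those of nearly all random lists. Few of their members differed by 2-fold, at most 4 in any of these lists in the lower direction. The remaining lists did not stand apart or had too few members. Among lists that stood apart, the interval of the median included 0 for mesenchymal (-0.96 to 0.03), endothelial (-1.04 to 0.10) and macrophage markers (-0.57 to 0.07). The same held for acute phase genes (-0.69 to 0.21). Cell cycle genes (0.35, percentile 98.22) did stand apart with quantile and loess scaling (0.28 and 0.22) and with the floor at the array median (0.44), as did complement genes with that floor (-0.71). Among acute phase genes Hamp was 8.56-fold lower and Saa3 1.71-fold higher. The chemokine gene Ccl24 went the other way from most, from 0.985 to 18.2.

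Among 8303 genes compared between the mutants, 258 were at least 2-fold higher and 403 at least 2-fold lower in the array labelled double-deficient, and 13 and 112 were so by 4-fold. Higher genes made up 39.0% of the calls as deposited, 26.0% after cyclic loess and 26.8% after centring. The median of all genes compared was 0.11, against -0.01 after loess. Relative to it, erythroid genes lay at 0.64 and interferon-stimulated genes at -3.06.

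The next question was how many of the differences seen without DNase II were undone in the double mutant. Of the 643 genes at least 2-fold higher in the array labelled DNase II-deficient, 352 were at least 2-fold lower again in the array labelled double-deficient, 464 were within 2-fold of wild-type and 174 were still at least 2-fold above it. Of the 517 lower genes, 215 were at least 2-fold higher again, 476 were within 2-fold of wild-type and 40 were still at least 2-fold below. The 2 differences share the array labelled DNase II-deficient, so some reversal arises by chance. In 100 simulations of arrays without any genotype effect, 39.7% of higher genes came back by 2-fold, against the 54.7% observed. For lower genes these shares were 30.1% and 41.6%. Within 2-fold of wild-type lay 70.0% of higher genes in the simulations and 72.2% in the arrays, nearly the same. For lower genes these shares were 59.9% and 92.1%. Shares rest on different bases, since the simulations held 131.63 higher and 129.74 lower genes on average, against 643 and 517. Of higher genes, 29.6% stayed 2-fold above wild-type in the simulations and 27.1% in the arrays. In number these were 38.95 on average (highest 57) and 174, and the larger number goes with the larger base. Of lower genes, 39.8% stayed 2-fold below in the simulations and 7.74% in the arrays. In number these were 51.61 on average (lowest 34) and 40, although the arrays held more lower genes to start from. The simulated noise was drawn from the differences between the double-deficient and wild-type arrays, which hold real differences too. That pair had the smallest typical spread, 0.27 against 0.49 and 0.40 in the comparisons with the array labelled DNase II-deficient. Noise particular to the array labelled DNase II-deficient is left out, and it would also make differences reverse. Among genes compared in both, 352 were higher and then lower, against a simulated mean of 52.21 (highest 68), and 203 lower and then higher, against 37.29 (highest 56). The simulations leave out real effects. Independent lists, which leave out the shared array, would share 31.5 and 14.1. The covariance of the 2 differences was -0.49, the simulated mean was -0.10 and their difference was -0.39. Part of the excess in counts and in covariance may come from the shared array, since a single array could not be split.

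The counts by group were as follows, with no test of the differences between groups. Like those above, they count genes that passed the level filter in DNase II-deficient minus wild-type, without that filter in double-deficient minus wild-type, so some exceed the counts given for that comparison below. Of the 35 interferon-stimulated genes that were 2-fold higher without DNase II, 6 were still at least 2-fold above wild-type in the double mutant: Cxcl10, Oasl1, Ifit1, Irf1, Zbp1 and Ifitm3. For interferon-inducible GTPases this held for 8 of 9, for cytokines and chemokines 11 of 13, for granulocyte and mast cell markers 9 of 10. It held for 5 of 5 acute phase genes, 3 of 11 MHC class I and antigen processing genes and 3 of 13 higher macrophage markers. Such counts depend on how large the first difference was, and the share of it that was left ordered the groups otherwise. The median share of the log2 difference left was 1.57% for the interferon-stimulated genes and 47.7% for the GTPases. It was 71.8% for cytokines and chemokines, 80.6% for granulocyte and mast cell markers and 56.8% for acute phase genes. For MHC class I and antigen processing genes it was 38.6%, and for higher macrophage markers 59.2%. None of 8 hypoxia genes and none of 18 erythroid genes remained 2-fold from wild-type. The 3 lower macrophage genes, Marco, Cd5l and Clec4f, all remained at least 2-fold lower.

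**Figure D2:**
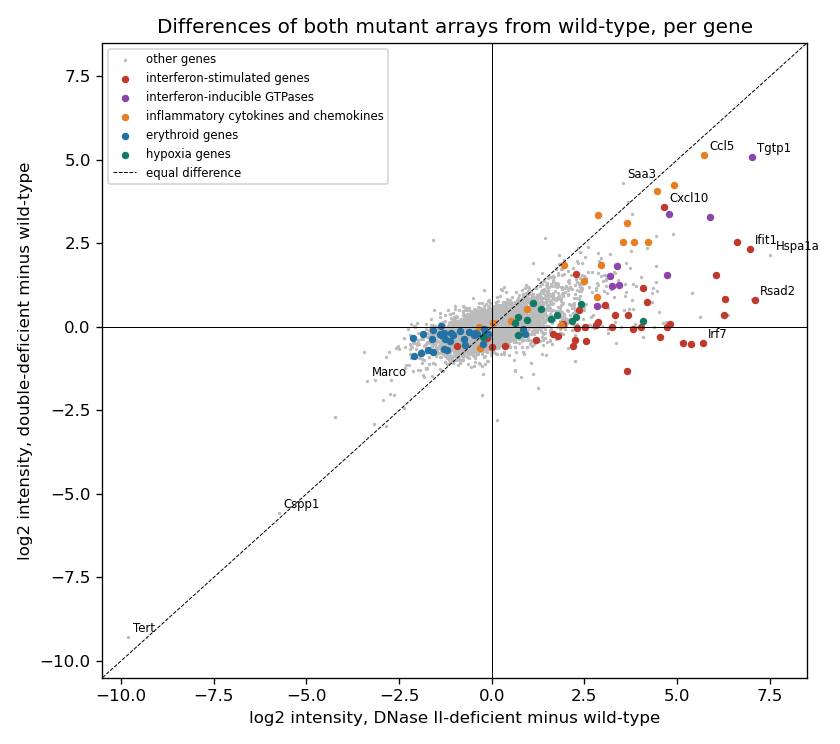
Log2 intensity difference from wild-type of the array labelled DNase II-deficient (horizontal axis) against that of the array labelled double-deficient (vertical axis), 1 point per gene compared, with 5 gene lists in colour and a dashed line of equal difference. Irf7 lies at 5.68 and -0.48, close to the horizontal axis, whereas Ccl5 at 5.73 and 5.15 and Saa3 at 3.53 and 4.30 lie near the dashed line.

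The comparison of the array labelled double-deficient with wild-type shows what differs without DNase II when the receptor is also missing. Several chemokine genes were higher. Ccl5 read 0.208 in wild-type and 7.38 in the double mutant, 35.5-fold higher. Ccl12 was 8.56-fold and Ccl2 5.84-fold higher, and Cxcl1, Ccl7 and Cxcl9, at the floor in wild-type, were at least 18.9-fold, 16.7-fold and 10.2-fold higher. Of 27 cytokines and chemokines, 9 were counted as at least 2-fold higher and none as lower, with a median log2 difference of 0.71 (percentile 100). Interferon-stimulated genes as a list did not stand apart, with a median of 0.01 (percentile 87.0), 5 of 40 at least 2-fold higher and 1, Ifi27, lower. That median is the value of the 4 members at the floor in both arrays, and without them it was 0.02. Cxcl10, which the interferon list holds and which is itself a chemokine, was 11.9-fold higher. Interferon-inducible GTPases had a median of 1.38 (percentile 100) and 8 of 12 at least 2-fold higher, with Tgtp1 at 33.8-fold and Gbp2 at 10.5-fold. That median was 0.68 with the floor at the array median. MHC class I and antigen processing genes had a median of 0.50 (percentile 100), with Tap1, Psmb8 and Psmb9 at least 2-fold higher, while B2m read 111.1 and 121.3.

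Granulocyte and mast cell markers were higher beside the chemokines, with a median of 1.13 (percentile 100). All 17 differed in the higher direction and 10 by at least 2-fold, Ngp at 2.89-fold and S100a8, from 68.4 to 163.7, at 2.39-fold. Macrophage markers had a median of 0.45 (percentile 100). Gpnmb was at least 10.3-fold, Msr1 3.77-fold and Ctss 2.29-fold higher, whereas Cd5l was 7.47-fold, Clec4f at least 7.78-fold and Marco 3.06-fold lower. Among acute phase genes (median 0.39, percentile 100) Saa3 was 19.8-fold higher and Saa4 6.85-fold lower, and the list no longer stood apart with the floor at the array median. The interval of the acute phase median, -0.16 to 1.52, included 0. p53 targets and cell death genes (0.37), lysosomal genes (0.34), nucleic acid sensing (0.31), mesenchymal markers (0.28) and hypoxia genes (0.26) had small positive medians above those of nearly all random lists. Of these, the interval for nucleic acid sensing included 0 (-0.10 to 0.67). Small negative medians were found for heme biosynthesis (-0.54), hepatocyte genes (-0.33), cell cycle genes (-0.31) and erythroid genes (-0.23). No erythroid, heme or hepatocyte gene differed by 2-fold. The remaining lists did not stand apart or had too few members. Embryonic globins were lower than in wild-type, Hba-x by 1.74-fold and Hbb-y by 1.68-fold, the opposite of the array labelled DNase II-deficient.

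**Figure D3:**
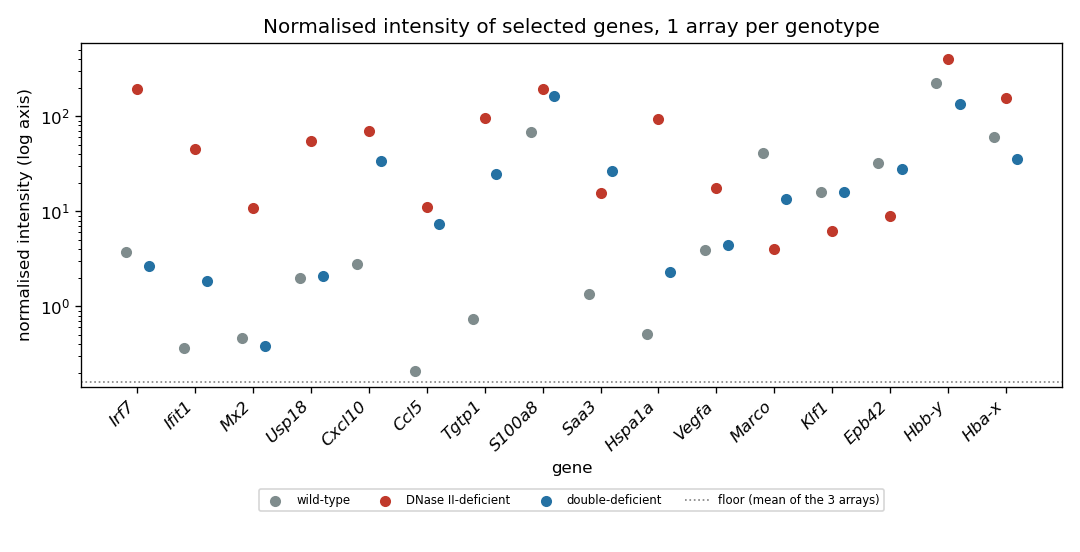
Normalised intensity on a log axis (vertical) of 16 genes (horizontal axis), 1 point per array, with the wild-type array in grey, the array labelled DNase II-deficient in red and the array labelled double-deficient in blue, and a dotted line at the mean floor. Irf7 reads 192.6 in red and 2.68 in blue, whereas S100a8 reads 193.7 and 163.7.

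Outside the lists, the survival gene Bcl2a1b, 1 of several near-identical copies, was 13.3-fold higher in the array labelled double-deficient than in wild-type, and Vnn3, Capg and the nuclear receptor gene Pparg were 5.12-fold, 4.69-fold and 4.65-fold higher. Car3 was 6.46-fold and Nfam1 5.35-fold lower. Among 8158 genes compared, 167 were at least 2-fold higher and 60 at least 2-fold lower, and 33 and 11 were so by 4-fold. The typical spread among genes of like level was 0.27 on the log2 scale, against 0.49 and 0.40 in the other comparisons.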

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

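Probes without a gene symbol were left out of the comparisons and hold signal that differs between arrays. Of 1734 such probes above the level filter, 18 were at least 4-fold higher and 5 at least 4-fold lower in the array labelled DNase II-deficient than in wild-type, and the largest positive difference was 43.3-fold, at 0.157 and 7.02. In the array labelled double-deficient 2 were at least 4-fold above wild-type and 2 at least 4-fold below, of 1713, and between the mutant arrays 3 were 4-fold higher and 12 4-fold lower in that array.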

How the results depend on the processing

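All alternatives were planned except centring, which was chosen after seeing the data. Of 46 list medians that stood apart, all kept their direction except that of hepatocyte genes in DNase II-deficient minus wild-type, which was near 0 and became 0.12, 0.13 and 0.21 with quantile, 75th percentile and loess scaling. With quantile and loess that list no longer stood apart (percentiles 97.32 and 98.45), because its random lists moved up too: the upper end of their range went from -0.09 to 0.13 and 0.19. No named gene counted as 2-fold different reversed, although Parp14, not so counted, turned from lower to higher without DNase II when its probes were averaged. Of the values of 936 named-gene differences under the alternatives, 295 moved by more than the spread among genes of like level and 5321 did not. The deposited values without further scaling are the main setting and so add nothing, and the level filters do not enter list medians. With the floor at the array median no interferon gene was left to give a list median. The cause of the shifts was not tested, except that a stricter filter or threshold leaves fewer genes by construction. Signal over background limits dim genes, whose folds depend on the floor.

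In DNase II-deficient minus wild-type, the 75th percentile filter gave 310 higher and 321 lower genes and the 3-fold threshold 336 and 123. Lower genes numbered 304 with loess and 298 with centring. In double-deficient minus DNase II-deficient the filter gave 158 and 192 and the threshold 45 and 194. In double-deficient minus wild-type the counts were 259 and 97 without a filter, 67 and 25 with the 75th percentile filter and 59 and 14 at 3-fold. Of genes higher without DNase II, 173 came back by 2-fold under the 75th percentile filter, and 96 stayed 2-fold above wild-type (102 with the floor at the array median). Of lower genes, 141 came back with loess and 142 under that filter, and 17 stayed 2-fold below wild-type under it and 62 without a filter.

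In DNase II-deficient minus wild-type, heme biosynthesis lay at -0.78, -0.92 and -0.75 with quantile, 75th percentile and loess scaling, granulocyte and mast cell markers at 1.65 with quantile and 1.74 with loess, and lysosomal and cell cycle genes at 0.74 and -0.51 with loess. In double-deficient minus DNase II-deficient, hepatocyte genes lay at -0.36 with loess. In double-deficient minus wild-type, erythroid genes lay at -0.15, -0.18 and -0.14 with the 3 scalings, and granulocyte and cell cycle lists at 1.26 and -0.21 with loess. With the floor at the array median, interferon-inducible GTPases lay at 0.68, and acute phase genes at 0.00799 no longer stood apart.

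Lists that did not stand apart in the main setting gained a call in 5 cases. Complement genes did so with the floor at the array median, at 0.85 in DNase II-deficient minus wild-type and -0.71 in double-deficient minus DNase II-deficient. Cell cycle genes did so in double-deficient minus DNase II-deficient, at 0.28 with quantile, 0.22 with loess and 0.44 with the floor at the array median.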

Other observations

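A few genes, picked after their values were seen, were highest in the array labelled double-deficient, and no list of such genes was fixed or tested. Cd74, the class II invariant chain, read 0.898 in wild-type, 2.43 in the array labelled DNase II-deficient and 5.73 in the array labelled double-deficient. H2-Eb1 and H2-Aa were below the floor in the array labelled DNase II-deficient, read 0.416 and 0.512 in wild-type, and were at least 10.3-fold and 8.98-fold higher in the array labelled double-deficient than in the array labelled DNase II-deficient. The eosinophil chemokine gene Ccl24 read 2.98, 0.985 and 18.2. Ccl20 was at the floor in wild-type, read 0.482 and 1.54 in the arrays labelled DNase II-deficient and double-deficient and was at least 9.50-fold higher in the latter than in wild-type, and the mannose receptor gene Mrc1 read 3.98, 2.78 and 7.24.

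Several genes that are bright in the wild-type liver were low in the array labelled DNase II-deficient and higher again, in part or in full, in the array labelled double-deficient. Kctd14 read 107.0, 15.6 and 63.1, the protease gene Ctse 50.4, 12.6 and 55.01, and Serpina1c, which resembles other Serpina1 copies, 56.0, 5.11 and 33.0. In the opposite direction, Ms4a4c and Trim30d read 0.726 and 0.969 in wild-type, 35.7 and 24.98 without DNase II, and 0.887 and 1.08 in the double mutant.

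The tests of array scaling were fixed before their results were seen, and all other tests in this part were chosen afterwards. Chemokine genes lay above wild-type in the array labelled double-deficient although interferon-stimulated genes as a list did not. The choice among the scalings tried made little difference to this. The median of cytokines and chemokines was 0.71 as deposited and 0.705 at the lowest over 3 other scalings. Over these the median of all genes compared went from -0.08 to -0.02, -0.02 and 0.00, a far smaller amount. The range of 95% of random lists ended at 0.16 or lower. That range is a weak check, because random lists are rescaled together with the list. A fault that none of these scalings corrects was not tested. Signalling left through the type I interferon receptor cannot be told apart from other inducers, because the lists tied to interferon went different ways. The median of interferon-stimulated genes was 0.0112, within the range of random lists, which ended at 0.0608. It is the value of 4 members at the floor in both arrays, but without them it was 0.0191, also below that end. Of the 35 members 2-fold higher without DNase II, 28 were within 2-fold of wild-type in the double mutant and 6 were still 2-fold above. Members of the whole list went both ways. Interferon-inducible GTPases and MHC class I genes stayed above their random lists, at 1.38 and 0.50. More myeloid cells in the tissue may account for part of it, since granulocyte and mast cell markers had a median of 1.13, or 2.19-fold. Macrophage markers had a median of 1.36-fold, and cytokines and chemokines as a list 1.64-fold, although Ccl5 differed by far more. How much a rare cell type could add to a single chemokine gene was not tested. Cell numbers and levels per cell cannot be told apart in whole tissue. An effect of the genotypes themselves stays open and untested, with 1 array each.

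Erythroid genes were lower and hypoxia genes higher in the array labelled DNase II-deficient. The choice among the scalings tried does not account for it. The erythroid median was -1.09 as deposited and -0.876 at the nearest to 0 over 3 other scalings. The hypoxia median was 1.32 as deposited and 1.45 at the lowest over these. The median of all genes compared went from -0.21 to -0.07, -0.07 and -0.00. Both lists lay outside their random lists, a weak check, because random lists are rescaled together with the list. A lower share of erythroid cells alone would raise markers of all other cells alike. The granulocyte median, however, lay 1.47 above the hepatocyte median, with intervals that did not overlap (lower end 0.92 against upper end 0.13). These intervals come from drawing members of each list and not from replicates. A lower share of erythroid cells beside other changes stays possible, because the test used no erythroid or hypoxia gene. A younger embryo could also show less definitive and more primitive red cell RNA, as the embryonic globin median of 0.849 would need, and with 1 array per genotype at the same labelled day this cannot be told apart from a loss of definitive cells.

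The Tert and Cspp1 probes were bright in the wild-type array alone, where Tert ranked 144 from the top of all probes. A fault of single spots may explain this, but there were 0 further probes of these genes to compare, so a spot fault cannot be told apart from a real difference. Only 3 probes in the wild-type array were at least 8-fold above both other arrays, against 55 in the array labelled DNase II-deficient and 1 in the array labelled double-deficient. No biological explanation was tested.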
